A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

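RNA from 6 cultures was hybridised to 6 arrays, 3 of wild-type diploid yeast and 3 of a strain described as a diploid with both copies of PUN1 deleted, all of the Σ1278b background, per the labels. Cells grew in rich YPD medium at 30 °C to an OD600 of 0.6, were washed, and spent 6 h in SLAD medium with 2% glucose and little nitrogen, per the labels' protocols. Polyadenylated RNA was selected with a purification kit and labelled with a one-cycle kit and biotin, per the labels' protocols. The values used are the deposited log2 probe set values of the authors, made with GCRMA, a method that adjusts background by probe sequence, per the submitters' processing notes. Those notes also list GCOS 1.1 and limma, with no version for GCRMA or limma and no order of steps. The log base is not stated and was taken as 2 from the range of the values. The medians over the tested probe sets lay close together, at 10.85 to 10.91 (log2). Over all probe sets on the array the medians were 6.85, 6.91 and 6.88 on wild-type replicates 1, 2 and 3. On deletion replicates 1, 2 and 3 they were 7.06, 7.05 and 7.09. Both medians were higher on every deletion array than on any wild-type array. No column of samples outside the series was present (0 columns). Array scanner files were not used here.

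Probe sets were named through the platform's annotation table and the gene table of assembly R64 of the reference, which served only for names, neighbours and chromosome membership. Of the 10928 probe sets, 7244 had 1 gene symbol in the platform table, 1 had several and 3683 had none. Of those without a symbol, 166 were control probe sets and 3517 were others; a probe set that the table does not list is unnamed here. The table of the reference changed 12 symbols. The test took the 5498 probe sets of S. cerevisiae genes, which stand for 5449 genes; 47 genes had over 1 probe set, none had probe sets called in opposite directions and 5 had some but not all called. Controls and the probe sets of Schizosaccharomyces pombe, a yeast whose genes the same array carries, were left out. Background was the 95th percentile of 1747 S. pombe probe sets, 5.68 (log2) on the means. Where a gene was at or below the background of every array of a group, the difference is given as a bound against that background, as "at least N-fold". The genome build of the probe design is not given in the sources used here, so no positions are printed.

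Differences are deletion minus wild type and were tested per probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, no covariates, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p of a gene comes from that fit. Gene lists were tested with camera on 1 probe set per gene, the brightest, with PUN1 left out and a preset inter-gene correlation of 0.01. Of 26 lists fixed before the data were examined, 24 were tested and 6 called, 3 higher and 3 lower; the genes flanking PUN1 and the marker genes were described gene by gene, and 1 of the called lists is not reported here. With an estimated correlation camera called 0 lists (2 at an unadjusted p under 0.05), and fry, which asks whether the genes of a list move one way on balance, called 6. Of these, 4 were also called by camera; fry called the cell wall and thiamine lists in addition and did not call ribosome biogenesis or the respiratory chain. The lists, the tests and the first alternatives were chosen before the data were examined. The genes named are PUN1 and its neighbours, the 15 genes with the largest difference in each direction that passed the threshold without overlap between groups and lay above background, up to 4 passing members of each list with the largest differences (2 where none passed), and all marker genes. Genes named outside this rule are said to have been chosen after their values were seen, or are members of the mating list that did not pass. MEP2 was also named after its value was seen. Figures were drawn with matplotlib 3.10.9.

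Replicate numbers are shared by the groups. The labels state no shared day, so the pairing was checked in the data: the deviations from the group means of arrays with the same number correlated across probe sets at 0.351, 0.213 and 0.112 for replicates 1, 2 and 3. All 3 exceed 0.1, and by that rule the numbers pair the arrays. Of the arrays with different numbers, wild type replicate 2 with deletion replicate 3 and wild type replicate 3 with deletion replicate 2 also correlated, at 0.183 and 0.161, above the 0.112 of replicate 3, so the pairing of replicates 2 and 3 is weak. The fit without the block stays the one reported.

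RNA quality was read from control probe sets. The 25S ribosomal RNA control was at 12.8, 9.06 and 8.85 (log2) on wild-type replicates 1, 2 and 3 and at 9.07, 11.3 and 12.5 on deletion replicates 1, 2 and 3, which did not separate the groups (exact permutation test, two-sided p = 0.8, the smallest possible being 0.1). The difference between 3′ and 5′ probe sets of the ACT1 control was 0.37 ± 0.03 in wild type and 0.36 ± 0.01 in the deletion (SD, n = 3). That of SPT15 was 1.47 ± 0.06 and 1.42 ± 0.04, and that of WBP1 was 1.30 ± 0.05 and 1.38 ± 0.05. The arrays of the groups did not overlap for WBP1, whose difference of 0.08 had an exact permutation p of 0.1, two-sided, the smallest possible.

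Alternatives were a moderated variance with trend and robust settings, a filter on dim probe sets, a further quantile normalization, median centring, all probe sets on the array, 1 probe set per gene, a replicate block, array weights, leaving out each array, stricter thresholds, and for lists an estimated correlation, fry and ranks. After the data were seen, the 25S signal as a covariate, leaving out the 3 arrays with a 25S signal above 10 (log2), and leaving out the mating-type list were added. The steps were tested on simulated values for the comparison of deletion with wild type over 5498 probe sets. Of the changes simulated at 0.5, 1 and 2 (log2), 92.5%, 97% and 100% were recovered, with 5 false calls among 198. A simulated shift of 0.3 of the autophagy list was called with 0 of the 23 other lists. The simulated values were drawn independently for each probe set, without correlation between genes. In the data the estimated correlation reached 0.81 for ribosome biogenesis, so the simulation cannot show how often camera calls lists falsely here.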

Results

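Messenger RNA of budding yeast of the Σ1278b background, a strain background that forms filaments when nitrogen is scarce, was measured on 6 one-colour expression arrays. Of these, 3 carried RNA of a wild type and 3 carried RNA of a strain described as homozygous for a deletion of PUN1, which encodes a plasma membrane protein. Both strains, labelled diploid, had spent 6 h in low-nitrogen SLAD medium before harvest. Each array gave 1 log2 value for each of 10928 probe sets, of which 5498 stood for genes of Saccharomyces cerevisiae and were tested. The median of the tested probe sets lay between 10.85 and 10.91 (log2) on every array, and 96.8% of them had a mean above background. Pairs of arrays within a group correlated across probe sets at 0.996 to 0.999, and pairs from different groups at 0.976 to 0.981; probe sets are not independent replicates. The number of arrays, 3 per group, limits the precision of each value.

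The comparison of deletion with wild type asks which transcripts depend on PUN1 under low nitrogen. All 3 deletion arrays also differed from wild type in mating-type genes, as described below. The comparison therefore cannot tell the loss of PUN1 apart from that difference. PUN1 itself (YLR414C) had the largest fitted decrease of the tested genes in the deletion arrays. Its value was 13.35, 13.50 and 13.55 (log2) on wild-type replicates 1, 2 and 3 and 8.33, 4.83 and 4.93 on deletion replicates 1, 2 and 3. The limma difference was -7.43 (SE 0.88, n = 3 per group, adjusted p = 0.00169). Deletion replicates 2 and 3 lay below the background of their arrays, which puts them at no more than 0.450% and 0.451% of the wild-type mean. Deletion replicate 1 lay above background, at 2.85% of the wild-type mean. Among 5 measured genes that flank PUN1, BER1, INA1, YLR415C and CDC73 differed by between -0.01 and 0.06 and did not pass the test. VPS36, a subunit of a membrane-sorting complex, was lower by a log2 difference of -0.19 (SE 0.04, adjusted p = 0.0226; 1 of the 5 also adjusted over the list alone). The call on VPS36 was lost without wild type replicate 2, deletion replicate 2 or deletion replicate 3 (adjusted p = 0.0604 to 0.0888).

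Of the 15 genes with the largest increases in the deletion arrays, 12 belonged to the list of haploid and mating-type specific genes. MF(ALPHA)1 and MF(ALPHA)2, which encode the alpha-factor pheromone, were 7.93 (SE 0.05) and 6.76 (SE 0.13) log2 units higher, and FUS3, the mitogen-activated kinase of the mating pathway, was 6.33 higher (SE 0.04, from 6.01 ± 0.05 to 12.34 ± 0.01, SD, n = 3 per group). Their adjusted p-values in limma were 7.8e-10, 2.63e-07 and 7.8e-10. MF(ALPHA)1 read 5.76 to 5.91 on the wild-type arrays, close to their backgrounds of 5.71 to 5.75, so the size of its difference rests partly on values near background. FUS3 read 5.95 to 6.05 on the same arrays, not far above those backgrounds, so the same limit applies to its difference. HMRA1, the gene of a1, which forms a repressor with alpha2 in a/alpha diploids, was at least 10.7-fold lower in the deletion arrays, where it was not above background on any array (adjusted p = 6.75e-06). HMLALPHA1, the gene of the alpha1 activator, was 5.29 higher (SE 0.06, adjusted p = 1.9e-08). The probe sets of HMRA1 and HMLALPHA1 also match the copies of the same genes at the mating-type locus, so the source of each signal within a pair of copies is uncertain.

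Of the 24 measured members of the list of haploid and mating-type specific genes, 17 were higher in the deletion arrays, none was lower and 7 did not pass the test; adjusted over the list alone the counts were 17 higher and 2 lower. The list was called higher by camera (adjusted p = 1.03e-13), and its call was lost with an estimated correlation (adjusted p = 0.424 with an estimated correlation). STE3, the receptor for a-factor, was 4.27 higher, the cell-surface agglutinin gene SAG1 was 3.68 higher, and AFB1, a gene outside the list that encodes a secreted a-factor barrier, was 4.18 higher. The 3 subunits of the mating G protein were higher as well, GPA1 by 4.80, STE4 by 3.20 and STE18 by 3.69. FAR1, which arrests the cycle in response to pheromone, was 5.17 higher, HO, the endonuclease of mating-type switching, 4.96 higher, NEJ1, a factor of end joining, 3.30 higher, and FUS1, needed for cell fusion, 3.12 higher. Their adjusted p-values lay below that of FUS1 (2.01e-06) or at it. FAR1 and HO were above background on 1 of the 3 wild-type arrays and STE18 on 2, so the sizes of these differences rest partly on values at background. The 7 members that did not pass were the genes specific to a cells, STE2, STE6, MFA1, MFA2, BAR1, AGA2 and ASG7, with a median difference of -0.21. IME4, a methyltransferase gene that promotes entry into meiosis, was lower, with a log2 difference of -3.50 (SE 0.08, adjusted p = 6.11e-07). On deletion replicates 2 and 3 it read 5.70 and 5.69, against a background of 5.67 on each, so that size rests partly on values near background.

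**Figure D1:**
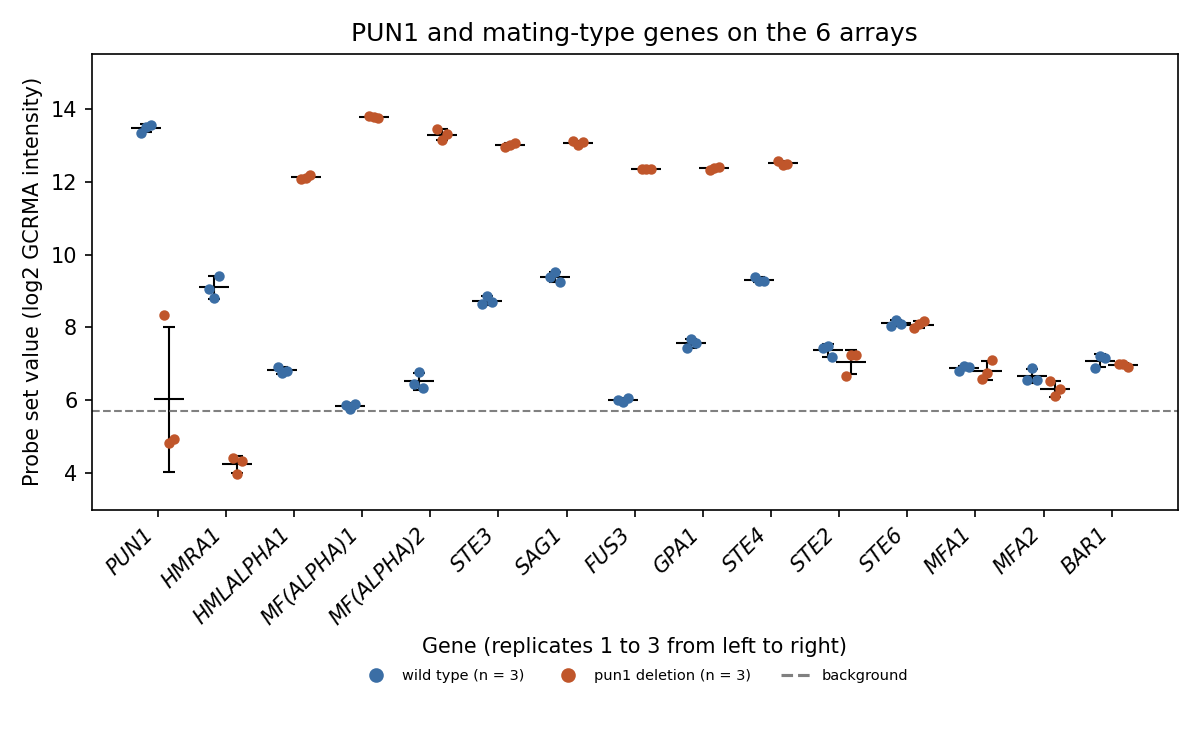
Values of PUN1 and 14 mating-type genes on the 6 arrays. The vertical axis is the log2 GCRMA value of the probe set, points are single arrays (wild type in blue, deletion in orange, replicates 1 to 3 from left to right), bars are the mean and SD of 3 arrays, and the dashed line is background; deletion replicate 1 of PUN1 stands at 8.33, and MF(ALPHA)1 stands at 5.84 in wild type and 13.78 in the deletion.

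Adhesion and filamentation genes were also higher. FLO11, which encodes the flocculin needed for filamentous and invasive growth, was 2.92 higher (SE 0.10, from 11.39 ± 0.21 to 14.31 ± 0.07, SD, n = 3 per group, adjusted p = 6.58e-06). Of the 15 measured members of the list of filamentation targets and adhesins, 10 were higher, none was lower and 5 did not pass; adjusted over the list alone 10 were higher and 1 lower. The anchor of the mating agglutinin AGA1 was 2.02 higher, the flocculin gene FLO10 1.54 higher and PGU1, a secreted endopolygalacturonase, 1.40 higher. The call of the list by camera (adjusted p = 0.000559) was lost with an estimated correlation (adjusted p = 0.424 with an estimated correlation). AGA1 also belongs to the mating list, and FUS3 was 6.33 higher in the same 3 arrays. The list of filamentous growth regulators, transcription factors and signalling proteins, held 11 higher, 12 lower and 15 members that did not pass out of 38 (12 higher and 13 lower adjusted over the list alone) and was not called (adjusted p = 0.723). Its mean was above 0 while its median and its test pointed down. SIP4, an activator of gluconeogenic genes, was 1.53 higher; the repressor gene NRG2 had a log2 difference of -1.04, MGA1 of -0.78 and MIT1, a regulator of FLO11, of -0.75.

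DSE2, DSE1, DSE4, PRY3 and SCW11 were among the 15 largest decreases in the deletion arrays. DSE2, which encodes a secreted wall-degrading protein, had a log2 difference of -3.48 (SE 0.16, adjusted p = 2.53e-05). DSE1 was at least 9.00-fold lower and was not above background on any deletion array (adjusted p = 2.58e-05). The glucanase genes DSE4 and SCW11 differed by -2.12 and -1.68 and the cell wall protein gene PRY3 by -2.08. The same 3 arrays had MF(ALPHA)1 7.93 higher than wild type.

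Amino acid biosynthesis was lower as a list. Of 44 measured Gcn4 targets, 24 were lower, none was higher and 20 did not pass (31 lower adjusted over the list alone). ARG1 and ARG3, enzymes of arginine synthesis, had log2 differences of -2.06 (SE 0.10, adjusted p = 3.27e-05) and -1.34, the branched-chain aminotransferase gene BAT1 of -1.46 and LEU4, the first step of leucine synthesis, of -1.37. The call by camera (adjusted p = 1.03e-13) was lost with an estimated correlation (adjusted p = 0.424 with an estimated correlation). LEU1, the isomerase of the leucine pathway, differed by -1.94 and OAC1, a mitochondrial carrier of oxaloacetate and isopropylmalate, by -2.25. Among the genes often used as strain markers, LEU2 differed by -1.35, LYS2 by -0.61 and HIS3 by -0.36, while URA3 was 0.56 higher; ADE2, at 0.38, did not pass (adjusted p = 0.0875). MET17 differed by -0.52, a call lost when any array other than wild type replicate 1 was left out (adjusted p = 0.0707 to 0.107). ADE2 passed without wild type replicate 1 or deletion replicate 1 (adjusted p = 0.0414 and 0.0262). Over the 6 measured markers, 1 was higher and 4 were lower, against 2 and 4 adjusted over the list alone; the list was not tested as a set. HMRA1 was at least 10.7-fold lower in the arrays with these lower levels.

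Other genes with large decreases belonged to no list. DIC1, the mitochondrial dicarboxylate carrier, differed by -1.90, RGI1 by -1.87, ATG41, a gene of autophagy, by -1.79 and YNR014W by -1.71, with adjusted p-values of 2.42e-05, 0.000497, 0.00213 and 0.000238.

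**Figure D2:**
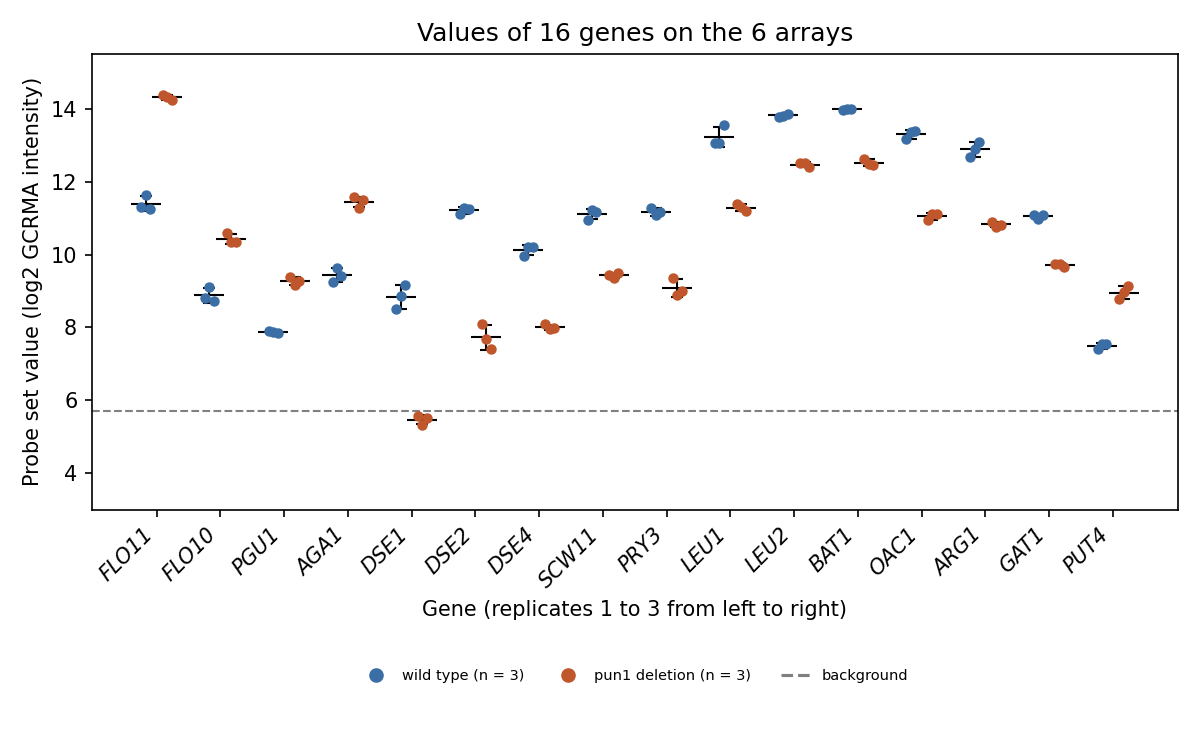
Values of 16 genes on the 6 arrays. The vertical axis is the log2 GCRMA value, points are single arrays with replicates 1 to 3 from left to right, bars are the mean and SD of 3 arrays, and the dashed line is background; FLO11 stands at 11.39 in wild type and 14.31 in the deletion, and DSE1 falls below background in the deletion.

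Nitrogen catabolite repression targets moved both ways. Of 29 measured members 9 were higher, 8 were lower and 12 did not pass (14 higher and 8 lower adjusted over the list alone), and the list was not called (adjusted p = 0.56). The proline permease gene PUT4 was 1.46 higher, while GAT1, a GATA activator of these genes, differed by -1.33, the ammonium permease gene MEP1 by -0.82 and the amino acid permease gene AGP1 by -0.72. MEP2, the ammonium permease that acts as a nitrogen sensor, did not pass at 0.11 (adjusted p = 0.132). In the same arrays FUS3 was 6.33 higher.

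Cell surface lists held changes of smaller size. Of 44 cell wall genes 12 were higher, 5 lower and 27 did not pass (13 and 5 adjusted over the list alone). Camera did not call this list (adjusted p = 0.137), and fry called it higher (adjusted p = 0.000795). PRM5 was 1.23 higher, the glucan synthase gene GSC2 1.19 higher and the mannoprotein gene TIR1 1.04 higher, while PIR1 differed by -0.87. Of 20 measured proteins of eisosomes and of the membrane compartment of Can1, a domain of the plasma membrane, 4 were higher, 4 lower and 12 did not pass, with the same counts adjusted over the list alone (list adjusted p = 0.914). YNL194C, a relative of the eisosome protein Sur7, was 1.38 higher, above background on 1 of the 3 wild-type arrays. The uracil permease gene FUR4 differed by -1.13 and MDG1 by -0.43, and SLM2 was 0.50 higher. The mean and median of this list lay above 0 while its test pointed down. MF(ALPHA)1 was 7.93 higher in the same arrays.

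Genes of carbon and energy metabolism were mixed. The respiratory chain and tricarboxylic acid cycle list held 12 higher, 3 lower and 28 members that did not pass out of 43 (14 and 4 adjusted over the list alone). It was called higher by camera with a median of 0.10 (adjusted p = 0.0164), but not with an estimated correlation (adjusted p = 0.996 with an estimated correlation) or by fry (adjusted p = 0.0804). The call was lost without the 3 arrays of high 25S rRNA signal (adjusted p = 0.794), and also without wild type replicate 1, deletion replicate 2 or deletion replicate 3 (adjusted p = 0.0526 to 0.105). SDH3 and SDH2, subunits of succinate dehydrogenase, were 0.36 and 0.31 higher and ACO1, aconitase, differed by -0.46. IDH2 differed by -0.42, a call lost without wild type replicate 2 or 3 or deletion replicate 3 (adjusted p = 0.0523 to 0.0641). In hexose transport, 3 of 18 members were higher, 2 lower and 13 did not pass, the same adjusted over the list alone, with a mean above 0 and a median and test below (adjusted p = 0.986). For 14 of the 18 the mean of the higher group lay above background. HXT4 was 2.16 higher, HXT7, whose probe set is shared with close relatives and is uncertain, 0.84 higher and HXT5 0.76 higher; MIG2, a glucose repressor, differed by -0.80. Glycolysis and fermentation held 2 higher, 2 lower and 14 that did not pass of 18, the same adjusted over the list alone (list adjusted p = 0.627), with ADH5 at -0.95 and PDC6 at 0.52. FUS3 was 6.33 higher in these arrays.

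Stress and growth lists changed little as sets. Of 43 general stress genes 11 were higher, 8 lower and 24 did not pass (11 and 9 adjusted over the list alone; list adjusted p = 0.946), the mean lying above 0 and the median and test below. DDR2 was 2.33 higher, the hydrophilin genes GRE1 and SIP18 1.61 and 1.24 higher, and the repressor gene XBP1 1.01 higher. Ribosome biogenesis held 1 lower gene, UTP15 at -0.21, and 57 that did not pass of 58, with 0 adjusted over the list alone. The list was called lower at a median of -0.07 (adjusted p = 0.013), a call lost with an estimated correlation (adjusted p = 0.996 with an estimated correlation) and without wild type replicate 1, deletion replicate 2 or deletion replicate 3 (adjusted p = 0.0658 to 0.528). It was not called by fry (adjusted p = 0.627) or after a further quantile normalization (adjusted p = 0.13). Without the 3 arrays of high 25S rRNA signal its direction turned, to a mean of 0.12 (adjusted p = 0.00147). UTP15 lost its call when any array other than wild type replicate 3 was left out (adjusted p = 0.0609 to 0.13). Of 127 cytosolic ribosomal protein genes, 3 were lower and 124 did not pass, with 1 lower adjusted over the list alone (list adjusted p = 0.279, and called lower after median centring at 0.0447). RPS9A differed by -0.51; RPL22B, at -0.34, lost its call without any array other than wild type replicate 1 and RPS22B, at -0.24, without wild type replicate 2 or 3 or deletion replicate 2 (adjusted p up to 0.111 and 0.0776). Each of these genes has a close paralog, and signal shared within a pair is uncertain. MF(ALPHA)1 was 7.93 higher in the same arrays.

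Among meiotic genes, 12 of 30 were higher, 3 lower and 15 did not pass (15 and 4 adjusted over the list alone; list adjusted p = 0.117, and called higher after median centring at 0.0447). For 22 of the 30 the mean of the higher group lay above background. Beside the lower IME4, SPR3, a sporulation septin, was 1.12 higher, SPS19 0.91 higher and SPO11, the meiotic break-forming enzyme, 0.68 higher. On wild type replicate 1 SPO11 read 5.84, close to the background of 5.75. Of 29 G1/S genes 7 were higher and 2 lower and 20 did not pass, the same adjusted over the list alone (list adjusted p = 0.89), with the cyclin genes PCL2, PCL1 and CLN2 at 0.79, 0.68 and 0.55. Of 24 G2/M genes 6 were higher, 1 lower and 17 did not pass (6 and 2 adjusted over the list alone; list adjusted p = 0.137), with the transcription factor gene SWI5 at 0.70. Of 10 histone genes 2 were higher and 8 did not pass, the same adjusted over the list alone (list adjusted p = 0.762). CSE4, the centromeric histone, was 0.38 higher; HHO1, the linker histone, was 0.17 higher, a call lost without wild type replicate 2 or deletion replicate 2 or 3 (adjusted p = 0.0507 to 0.059). FUS3 was 6.33 higher in the same arrays.

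Camera with its preset correlation called none of the nutrient lists that remained. The iron regulon held 2 higher, 7 lower and 17 that did not pass of 26 (4 and 8 adjusted over the list alone; list adjusted p = 0.137), with the siderophore transporter gene ENB1 at -0.93 and the copper pump gene CCC2 at -0.54. Without wild type replicate 1 the iron list was called lower (adjusted p = 0.0190), and likewise without the 3 arrays of high 25S rRNA signal (adjusted p = 0.0277). Sulfur assimilation and methionine held 3 higher, 6 lower and 18 that did not pass of 27, the same adjusted over the list alone (list adjusted p = 0.279), with MET6, methionine synthase, at -1.23, MET13 at -1.19, STR3 at -1.01 and the sulfate permease gene SUL2 at 0.63. The phosphate regulon held 5 higher, 2 lower and 12 that did not pass of 19, the same adjusted over the list alone (list adjusted p = 0.996), with PHM8 at 0.88, PHM6 at 0.65 and VTC3 at -0.39; its mean and median lay above 0 and its test below. Thiamine synthesis and uptake held 5 higher and 9 that did not pass of 14 (6 higher adjusted over the list alone; list adjusted p = 0.0903), with the thiamine transporter gene THI7 at 0.80. For 12 of these 14 genes the mean of the higher group lay above background. This list was called higher by fry (adjusted p = 0.0361), and by camera with the filter on dim probe sets, with array weights and without deletion replicate 1 (adjusted p = 0.0391, 0.0387 and 0.0338). Autophagy held 4 higher, 2 lower and 19 that did not pass of 25, the same adjusted over the list alone (list adjusted p = 0.986), with ATG22 at 0.51. Ergosterol synthesis held 1 higher gene, HES1, and 25 that did not pass of 26, the same adjusted over the list alone (list adjusted p = 0.986); HES1 was at least 1.37-fold higher and not above background in wild type. HMRA1 was at least 10.7-fold lower in the same arrays.

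**Figure D3:**
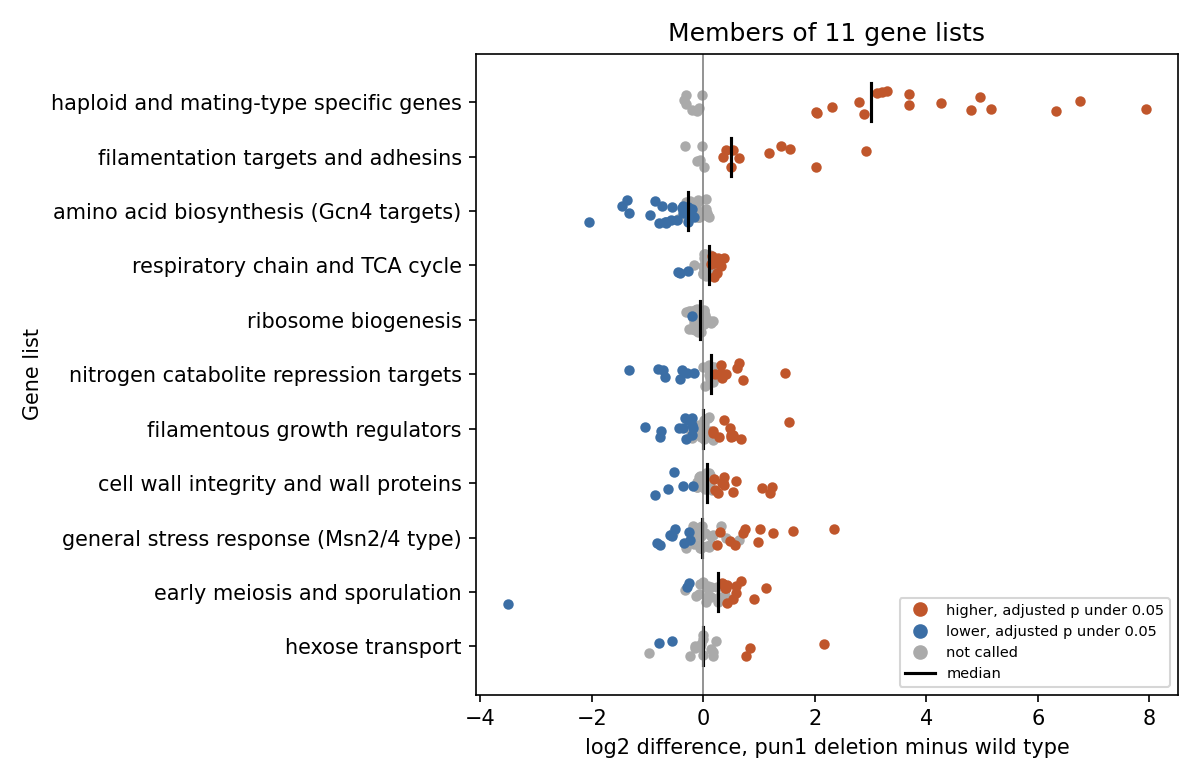
Differences of the members of 11 gene lists. The horizontal axis is the log2 difference, deletion minus wild type, each point is a gene (orange higher and blue lower at an adjusted p under 0.05, grey not called), and the black bar is the median of the list; the mating list has a median of 3.01 and the amino acid list -0.27.

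Across all 5498 tested probe sets, 868 were higher and 540 lower in the deletion arrays at a Benjamini-Hochberg adjusted p under 0.05 in limma, together 25.6%. Of these 77 were higher and 42 lower by 2-fold or more, and 27 and 9 by 4-fold or more. The arrays of the groups did not overlap for 867 of the higher and all 540 of the lower probe sets; over all tested probe sets 44.8% showed no overlap, against 10% by chance. Without PUN1, HMRA1, HMLALPHA1 and the members of the mating-type lists the counts were 847 higher and 538 lower. IME4 is on none of those lists and is still counted among the lower. The balance between higher and lower depended on scaling, with 702 higher and 711 lower after centring each array on its median and 700 higher and 760 lower after a further quantile normalization. The higher count was 507 without deletion replicate 2 and 535 without deletion replicate 3, and the lower count was 313 without wild type replicate 2, 284 without deletion replicate 2 and 325 without deletion replicate 3.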

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

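Among probe sets outside the tested genes, 372 that the platform table does not name lay above background, of which 34 were higher and 18 lower in the deletion arrays; the signal of 5 of them differed by over 2-fold. Probe set 1777669_at was 2.66 log2 units higher than in wild type. Probe set 1776865_at was 1.43 higher. Another unnamed probe set was 1.11 higher. Probe set 1774184_at had a difference of -2.27. Probe set 1777097_at had a difference of -1.28. Of the S. pombe probe sets, used as background, 1 was called higher and 11 lower.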

How the results depend on the processing

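The 25S rRNA settings and the setting without mating-type genes were chosen after seeing the data. The PUN1 difference kept its direction and its call in every setting run. Its smallest size was -5.19, without the 3 arrays of high 25S rRNA signal; without deletion replicate 1 both deletion arrays left lie below background, and PUN1 was at least 7.79 (log2) lower. Leaving out each array gave 507 to 874 higher and 284 to 560 lower probe sets. Array weights gave 892 lower. Without the 3 arrays of high 25S rRNA signal, which leaves wild type replicates 2 and 3 and deletion replicate 1, 447 were higher; the lone deletion array is assumed there to vary like the wild type. A threshold of 0.01 gave 416 higher and 236 lower, and a change of at least 2-fold 77 and 42, both by construction fewer. The replicate block gave 956 higher and 604 lower probe sets; it moved neither count by over 1.5 times and changed no call on a list or named gene. With an estimated correlation camera called 0 lists (2 at an unadjusted p under 0.05), and 6 at the preset one. The list of ribosome biogenesis reversed without the 3 arrays of high 25S rRNA signal, to a mean of 0.12 (adjusted p = 0.00147, against 2.11e-06 to 0.528 under the other fits of camera at the preset correlation, 0.627 with fry and 0.996 with an estimated correlation, all lower); the cause was not tested. The respiratory list was not called in that setting (adjusted p = 0.794). Over the fits other than the main one and the named genes, 1755 values kept direction and side of the threshold. Of the rest, 81 (17 genes) fell short of it, 4 (1 gene) newly passed and 0 reversed. For lists, over the fits tested by camera at the preset correlation with all genes, the counts were 296, 8, 7 and 1. The stricter thresholds, the estimated correlation, fry, ranks and the setting without mating-type genes are not in these counts. Signal over background limits FAR1, HO, STE18, HES1, YNL194C, SFC1 and POT1 in wild type and HMRA1, DSE1, PUN1 and ASG7 in the deletion, whose differences are sizes against background. MF(ALPHA)1 and FUS3 in wild type and IME4 in the deletion lay above background on every array but close to it on some.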

Other observations

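The tests of mixed cells, pheromone signalling, alpha identity, a weaker response of 1 array and differences outside the mating-type genes were chosen only after the results were seen, as were the lists of this part. Of 20 genes used on carbon sources that cannot be fermented, 15 were higher in the deletion arrays, none was lower and 5 did not pass, with a median difference of 0.99. This list was assembled after its values were seen and was not tested as a set, so its count is not independent evidence of its direction. The dicarboxylate carrier gene SFC1 was 2.15 higher (SE 0.18) and the lactate permease gene JEN1 1.88 higher (SE 0.10). The fructose bisphosphatase gene FBP1 and the malate synthase gene MLS1 were 1.75 higher each, POT1 and POX1 of fatty acid oxidation 1.76 and 1.40 higher, the alcohol dehydrogenase gene ADH2 1.54 higher and their activator gene ADR1 1.11 higher. Values of SFC1 and POT1 lay above background on 1 and 2 of the 3 wild-type arrays. PCK1, ACS1, ALD4, MDH2 and CIT2 did not pass, with differences between -0.09 and 0.38.

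Targets of Leu3, the activator of branched-chain amino acid synthesis, were lower: 12 of 13 listed genes were lower and LEU3 itself did not pass at 0.08, with a median of -1.35. OAC1 differed by -2.25, LEU1 by -1.94, the aldehyde dehydrogenase gene ALD5 by -1.61 and the malic enzyme gene MAE1 by -1.35. Of the 13, 6 also belong to the list of Gcn4 targets, whose regulator GCN4 did not pass at 0.05. The list was assembled after these values were seen, so its count is not independent evidence of its direction.

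The array also carries control probe sets along URA3, often used as a marker in strain construction. Its 3′ probe set was 0.64 higher (SE 0.12) and its middle one 0.49 higher (SE 0.05) in the deletion arrays, while the 5′ one, at 0.05 (SE 0.06), did not pass (adjusted p = 0.658 in limma over all probe sets on the array).

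The mating-type genes of the deletion arrays differed from those of wild type, where HMRA1 was above background on all 3 arrays. MATalpha cells mixed into cultures that otherwise stayed a/alpha are argued against by HMRA1, whose difference of -3.42 or beyond leaves no more than 9.34% of the wild-type level. Stronger pheromone signalling in a/alpha cells is argued against by the alpha-specific genes, all 5 of which were higher, with a median of 4.27. These 5 are all among the 15 largest increases that make up the pattern, so their count is not an independent test. Loss of a whole chromosome III copy is argued against by the median of 144 genes of that chromosome, 0.024 (SE 0.013) above that of the other chromosomes. A candidate explanation is alpha identity of the deletion strain, under which the 7 a-specific genes would stay near wild type. Mixed-in MATalpha cells would leave them there too, so their median of -0.21 does not separate the explanations. Under alpha identity the 12 genes that a1-alpha2 represses would be higher, and all of them were. Of these 12, 11 belong to the mating list already found higher, so their count is not an independent test. Mixed-in MATalpha cells would raise them too, so these genes do not separate the explanations. The labels call the strain diploid and name no mating type; whether such cells were haploid or diploid, and whether a1 was lost from the genome or silent after the loss of PUN1, was not tested.

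PUN1 signal in deletion replicate 1 stood at 2.85% of wild type, while replicates 2 and 3 lay below background. With replicates 2 and 3 set at background, replicate 1 lacked at least 34.1% of the PUN1 decrease. Under a weaker response of replicate 1 as a whole, this predicts a median of -1.09 or lower for 26 genes. These are the genes over 2 (log2) higher in replicates 2 and 3 than in wild type. Their median in replicate 1 was -0.032 (SE 0.049), which argues against a weaker rise of these genes. They include the 15 largest increases, of which 12 are on the mating list. A mating-type difference may account for those, so their level need not follow PUN1. A weaker response to the loss of PUN1 alone is therefore not excluded. Carry-over of wild-type RNA stays open and may account for the signal, since the 9 genes over 2 (log2) higher in wild type had a median excess of 0.20 in replicate 1 (SE 0.07), against a predicted 0.18. Gene by gene the match was poor, with HMRA1, IME4, DSE1 and OAC1 (4 genes, of which HMRA1 and DSE1 were below background in the deletion) under 0.5 of their predicted excess and PRY3 and RGI1 over 2 times theirs. No biological explanation was tested.

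Differences outside PUN1 and the listed mating-type genes numbered 1385 probe sets, IME4 among them. Without the members of the mating list camera called 5 lists at its preset correlation. With an estimated correlation and all genes it called 0 lists (2 at an unadjusted p under 0.05). A mating-type difference between the strains in place of the loss of PUN1 may account for any of them, and the causes cannot be told apart, because 3 of 3 deletion arrays carried FUS3 over 2 (log2) above the wild-type mean. That includes FLO11, the DSE genes and the amino acid genes. A deletion array without the mating-type difference would be needed to separate them.

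The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. Each split other than the real one mixes arrays of both strains, so differences between the strains widen the spread within its groups. Low counts of probe sets in those splits are partly built in, and no conclusion is drawn from them. For higher probe sets 1 split, the real one, reached 868, and the highest other gave 0; for lower probe sets 1 split, the real one, reached 540, and the highest other gave 0. For gene lists called, 4 splits reached the real 6, and the highest other gave 11, with wild type replicates 1 and 3 and deletion replicate 1 in a group. The same-numbered arrays are parted by 4 of the splits, the real one and 3 others, and those 3 called 0 probe sets in limma and at most 6 lists. Over the splits other than the real one, limma gave 29 to 349 probe sets at an unadjusted p under 0.05, against 2146 for the real one.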
